A study of Mus musculus with 2 samples.

How the data were processed

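H3K27me3, the trimethylation of lysine 27 of histone H3 that Polycomb repressive complex deposits on silenced genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic heart at day 11.5. Per the labels, the tissue came from mixed-sex embryos of the B6NCrl strain, and there were 2 biological replicates, each combining 2 technical replicates. Replicate 1 was made from 109 embryos, and the number for replicate 2 was not given in the sources used here. The labels place the size range of the libraries at 300 to 500 bp. There was 1 group and no other condition, so no group was compared with another.

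The deposited data were 4 peak lists on the mm10 build: 1 for each replicate, 1 for the pooled replicates and 1 of replicated peaks. The samples' deposited file descriptions state that the replicated list was derived from both replicate lists and the pooled list, and every replicated peak was an identical row of the pooled list. The rule that made a peak a replicated one, the aligner and the peak caller were not given in the sources used here. The lists have no header line, so the columns were read by the narrowPeak format and checked against their values. The authors' fold enrichment of each peak over background is a ratio, and it was used only to describe peaks and to rank genes. Genes were ranked by its mean over both replicates' lists or, where marked by 1 replicate alone, within that list. For each gene the fold was that of the highest peak overlapping the 2 kb window around its 5' end. Such a peak can reach beyond the window and be shared by neighbouring genes. The authors' −log10 p and −log10 q of each peak were used for filtering, and the deposited score and summit position were not used. The lowest deposited −log10 p was 2.04 in replicate 1 and 2.01 in replicate 2, so the lists were permissive, and 62.8% and 60.2% of their peaks had a −log10 q of at least 2. The files hold no read counts, so the depth of the libraries is unknown and no value could be weighted by it. A base outside a peak was not called, which does not show that it lacks the mark.

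Genes were taken from GENCODE release M21 on the same build, and sequence from the matching GRCm38 reference. No peak ended beyond its chromosome. Chromosomes 1 to 19 and X were used. A protein-coding gene was called marked when at least 200 bp of the 2 kb window centred on the 5' end of its gene record (1 kb either side) were covered by replicated peaks. There were 21755 such genes. Genes that share a window, as neighbours in clusters do, share peaks. CpG-rich genes had a CpG observed/expected ratio of at least 0.6 and a GC content of at least 50% in the 1 kb around the 5' end. Wide domains were replicated peaks merged over gaps of at most 1 kb and at least 10 kb long.

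Replicates were compared by the Jaccard index, the percentage of bases called in either list that were called in both, beside 100 seeded circular shifts of replicate 2's peaks along each chromosome. Shares of genes were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 18 gene lists and a threshold of 0.05. Shares of lists carry 95% Wilson intervals, which cover counting error over genes only. Fisher's test takes genes as independent, so marks were also rotated 10000 times along the gene order, and each list was also tested against 5 genes per member matched on CpG and GC. Values per replicate are means ± SD of 2 replicates where both are given together, and no p-value rests on differences between the replicates. The lists, thresholds, named-gene rule and tests, other than those named at the end of this paragraph, were fixed before the data were examined. The alternatives fixed then were peaks with a −log10 q of at least 2, each replicate's list alone, bases called in both replicates, the pooled list, coverage minimums of 1 bp and 1000 bp, windows of 0.5 kb and 2.5 kb, all annotated transcripts' 5' ends, a stricter CpG class, and other merging gaps. Lists of equal length and matched genes outside all lists were added after seeing the data. So were the comparisons of gene families by symbol, of marking across CpG classes and of CpG classes on X. The comparisons of the X ratio with lists of equal length and outside genes, and of escape genes, were added then as well. Tests of the lists in wide domains were not in the plan either, which only counted the domains and their genes.

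The named genes followed this rule. In each list these were up to 4 marked members with the highest mean window coverage over both replicates, ties going to the higher fold, and up to 3 unmarked members first in list order. To these were added the Hox genes with the highest and lowest coverage in each cluster, genes with a 5' end in the 10 widest domains, and the 5 marked genes with the highest mean fold. The rule also took the 3 genes with the highest fold among those marked by 1 replicate and without a called base in the other, in each direction, and the members that go against a developmental list when they are 5 or fewer. Other genes named below were chosen after their values were seen. The lists of endothelial, epicardial, blood, neural and liver or pancreas genes stood for other cell types that a dissected heart could hold. Of the list members 5 were not protein-coding (Amy2b, H19, Kcnq1ot1, Meg3 and Airn) and were left out of the tests.

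The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The list test was tested on simulated data over 21755 genes with lists of 28 genes in 400 simulations. It passed the adjusted threshold in 0.50% of simulated lists marked as often as other genes (16%), in 54.3% of those marked at 40% and in 100% of those marked at 90%. Simulated list members were drawn at random, marks came in short runs of neighbouring genes, and the other lists in the adjustment did not differ. These rates need not hold for lists of neighbouring genes, such as the Hox genes, or where several lists differ. Interval arithmetic matched a base-by-base count in each of 200 random draws.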

Results

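H3K27me3 peaks were called in hearts of day 11.5 mouse embryos in 2 biological replicates of 1 group. Replicate 1 had 117679 peaks over 50.5 Mb, or 1.97% of the genome, and replicate 2 had 99275 peaks over 40.9 Mb, or 1.60%. The authors' pooled list had 65340 peaks over 34.8 Mb, and their replicated list had 49455 peaks over 31.2 Mb. Median peak widths were 264, 267, 296 and 357 bp in these lists, in that order, and the widest replicated peak spanned 25439 bp. Sequencing depth is unknown, since the files hold no read counts.

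Both replicates marked all Hox genes and all listed neural factors, but many of the bases called in either were called in that replicate alone. They shared 23.9 Mb, and the Jaccard index was 35.4%, against a mean of 0.90% and a maximum of 1.15% in 100 circular shifts. Of the bases called in replicate 1, 47.4% were called in replicate 2, and the reverse share was 58.5%. At gene 5' ends 4760 genes were marked by replicate 1's list and 4031 by replicate 2's, of which 3558 were shared, 68.0% of the genes marked by either. Across all genes, which are not independent replicates, window coverage in the replicates had a Spearman correlation of 0.82, and of 0.81 over the 5966 genes with a called base. Genes called by 1 replicate alone included Speg, a muscle kinase gene, with 45.5% of its window covered in replicate 1 and 0% in replicate 2, and Ptprs, a receptor phosphatase gene, with 34.7% and 0%. Tppp3 had 25.6% in replicate 1 and 0% in replicate 2, whereas Gm9833, Akna and Prss28 had 0% in replicate 1 and 18.9%, 17.4% and 12.3% in replicate 2. Speg, Ptprs, Tppp3, Gm9833 and Akna were nevertheless marked in the replicated list. Of the replicated peaks 85.9% overlapped a peak of both replicates by at least 1 bp, so that list is not limited to regions called in each replicate. It marked 98 genes without a called base in replicate 2 and 19 without one in replicate 1. Of its 3566 marked genes, 3318 were among the 3558 marked by both replicates' own lists, so each set holds genes that the other lacks.

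The replicated peaks marked 3566 of 21755 protein-coding genes (16.4%). Marked genes were ranked by the fold of the highest peak over the window, as a mean of both replicates. First were Wnt7b, a Wnt ligand, at 13.6 ± 0.33 (SD, n = 2), and Bhlhe23, a neural and retinal transcription factor, at 13.3 ± 0.53. Next came Kcnc1, a neuronal potassium channel, at 13.2 ± 2.89, Dio3, the thyroid hormone inactivating deiodinase, at 13.1 ± 2.39, and Hs3st2, a heparan sulfate sulfotransferase, at 13.0 ± 0.98. The window was covered in full at 512 marked genes and over at least 1000 bp at 2021. The median covered share of marked windows was 70.4% in replicate 1 and 51.5% in replicate 2. Promoter windows took 13.2% of the replicated bases against 1.60% of the genome, an 8.27-fold excess. Exons took 10.5% against 3.37%, introns 37.6% against 36.2%, and sequence outside genes 38.7% against 58.8%. In the replicates' own lists the promoter share was 10.1% and 9.79%.

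All 39 Hox genes, which set positional identity along the body axis, lay under the mark in both replicates. The Hoxc cluster (chromosome 15, 102921103 to 103036852, mm10) was covered over 95.3% ± 0.79 of its length (SD, n = 2), Hoxa (chromosome 6, 52155590 to 52260880) over 91.6% ± 4.95, Hoxd (chromosome 2, 74668310 to 74765142) over 88.4% ± 4.59 and Hoxb (chromosome 11, 96194316 to 96368256) over 76.0% ± 2.76. These stood beside 1.97% and 1.60% of the genome. The windows of Hoxa6, Hoxb13, Hoxc10 and Hoxd1 were fully covered in both replicates. The lowest in each cluster were Hoxa9 at 71.3% ± 14.1, Hoxb3 at 75.6% ± 14.1, Hoxc5 at 94.8% ± 1.34 and Hoxd4 at 79.0% ± 5.41. Hoxd3 shared nearly the same window as Hoxd4 and the same value. The Hoxc5 record begins at 102967443, inside the window of Hoxc10, which begins at 102966796. The lowest and highest Hoxc windows therefore overlap.

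**Figure D1:**
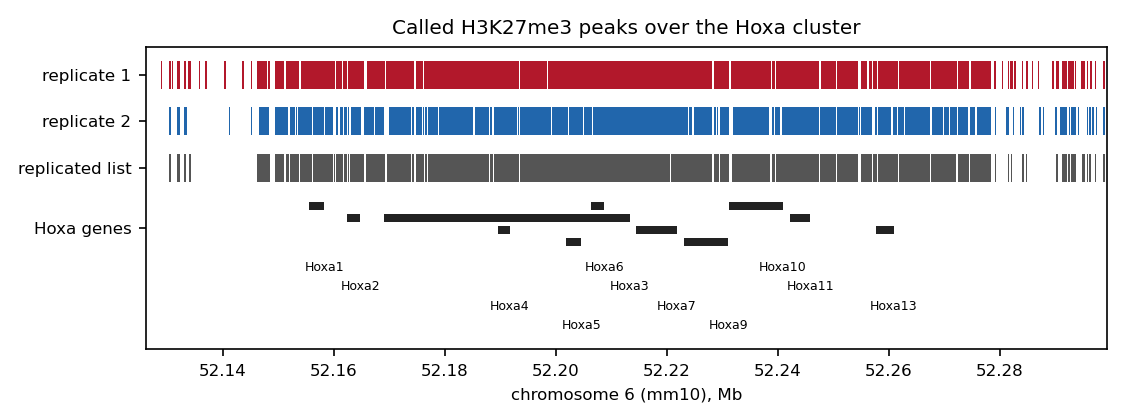
Called H3K27me3 peaks over the Hoxa cluster on chromosome 6 (horizontal axis, mm10 position in Mb), as blocks for replicate 1, replicate 2 and the replicated list, above black bars for the annotated Hoxa gene records, each named below its right end. Peaks cover 95.1% of the cluster in replicate 1 and 88.1% in replicate 2, and thin out on both sides.

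Merging neighbouring replicated peaks gave 612 domains of at least 10 kb, and the widest lay at the 4 Hox clusters. They spanned 168 kb at Hoxc, 133 kb at Hoxa, 112 kb at Hoxb, from Hoxb9 to Hoxb2, and 111 kb at Hoxd, where the domain began beyond the neighbouring homeobox gene Evx2 and ended before Hoxd1. Hoxb13 and Hoxb1, named after their values were seen, lay in separate domains of 46.4 kb and 16.0 kb. Next were Pax7, a neural crest and muscle stem cell factor, at 82.5 kb, the neural factors Zic4 and Zic1 at 62.2 kb, the ephrin receptor gene Epha8 at 56.1 kb, the cadherin gene Cdh22 at 53.5 kb and the kidney and hindbrain factor Pax2 at 51.6 kb. A domain of 67.5 kb on chromosome 7 (29417317 to 29484782) held no annotated gene 5' end and lay within the record of Sipa1l3. The 5' ends of 491 protein-coding genes fell in 400 of the domains. Among the lists, 38 of 39 Hox genes (adjusted exact p = 2.22e-61) and 47 of 52 neural factors (adjusted exact p = 1.89e-71) lay in wide domains. So did 8 of 28 cardiac factors (adjusted exact p = 3.42e-07), against 1 of 35 sarcomere genes (adjusted exact p = 0.708, Fisher's exact tests). Of the genes outside each of these lists, 2.05% to 2.26% lay in wide domains. Fisher's test takes genes of the same domain as independent, which Hox genes of a cluster are not. Rotation along the gene order was not run for these tests, which were not planned. The number of domains depended on the merging gap: it was 33 with no gap merged and 1248 with gaps of at most 3 kb.

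Transcription factors of other tissues were marked nearly throughout. All 52 neural factors were marked (adjusted exact p = 9.52e-41, Fisher's exact test), and Six3, Sox1, Lhx5 and Phox2a were fully covered in both replicates. Of somite, skeletal muscle and limb factors 21 of 26 were marked (80.8%, adjusted exact p = 3.11e-12), with full coverage of Myod1, the master regulator of skeletal muscle, and Lbx1. The exceptions were Myf5, Myf6, Myog, Tbx6 and Msgn1. Of endoderm and gut factors 18 of 21 were marked (85.7%, adjusted exact p = 1.70e-11), among them Neurog3, Insm1 and Foxa2 with full coverage. Hnf1a, Hnf4a and Isx were not marked at the 5' end of the gene record, though Hnf1a had 20% in replicate 1 and 0% in replicate 2. With all annotated transcripts' 5' ends the excess of the endoderm list over other genes rose from 69.4 to 75.9 points. Together 89 of 97 non-cardiac factors were marked, 91.8% (95% interval 84.6 to 95.8), against 10 of 27 cardiac factors, 37.0% (21.5 to 55.8), with the gene shared by these lists, Shox2, left out. The odds ratio was 18.9 (exact p = 1.23e-08, Fisher's exact test), and the difference passed the test in each replicate's own list.

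**Figure D2:**
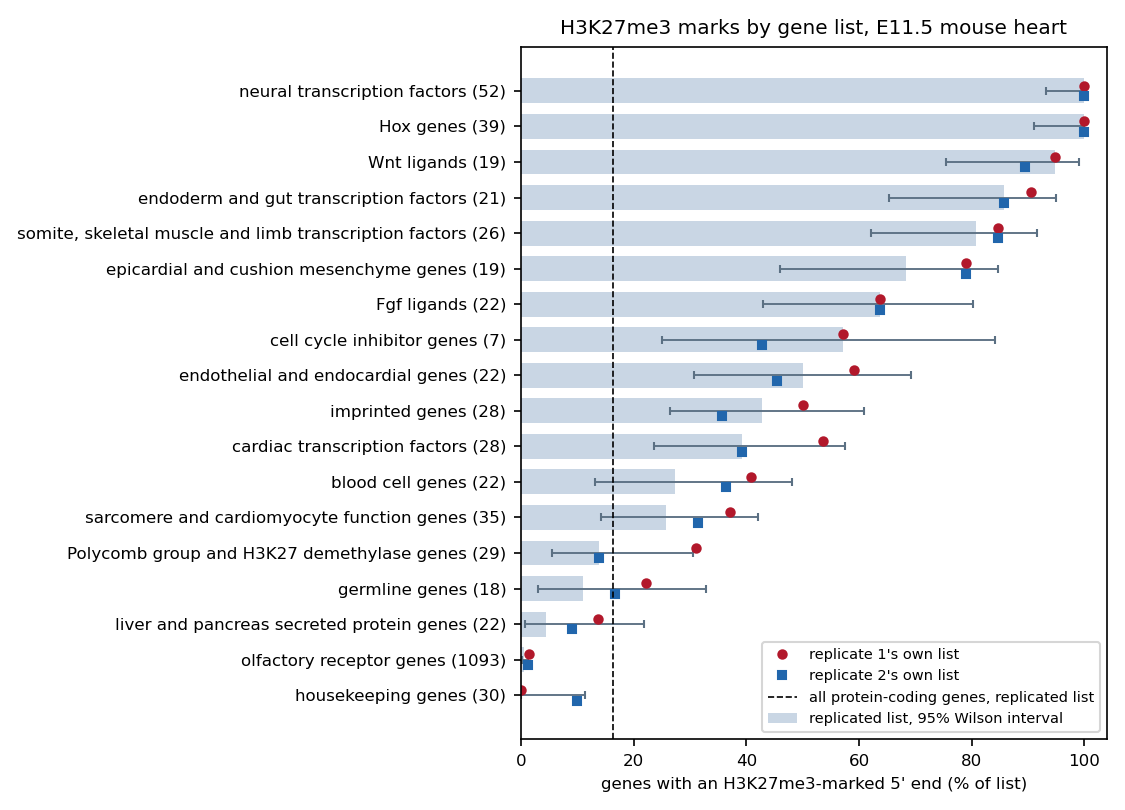
Percentage of the genes of each list with a marked 5' end (horizontal axis), with the number of genes tested in parentheses. Bars give the authors' replicated list with 95% Wilson intervals, red circles replicate 1's own list, blue squares replicate 2's own list, and the dashed line all protein-coding genes at 16.4%. Neural factors and Hox genes reach 100% in each list, and no housekeeping gene is marked in the replicated list.

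Cardiac transcription factors were divided. The mark lay on 11 of 28, 39.3% (23.6 to 57.6), more than on other genes at 16.4% (adjusted exact p = 0.00520, Fisher's exact test). The count was 15 in replicate 1's own list and 11 in replicate 2's. With windows of 2.5 kb it was 15, with all annotated transcripts' 5' ends 14, and with at least 1000 bp covered 9. Tbx1, a factor of the pharyngeal and second heart field, and Irx4, a ventricular factor, were fully covered in both replicates, while Hand1 reached 85.0% ± 21.3 and Shox2, a factor of the sinus node, 80.6% ± 4.84 (SD, n = 2). The other marked members, named after their values were seen, were Nkx2-5, Tbx2, Tbx3, Isl1, Irx3, Irx5 and Pitx2. Coverage at Nkx2-5, an early cardiac regulator, was 91.2% in replicate 1 and 30.7% in replicate 2. Gata4 and Gata6, core cardiac regulators, had 0% in both replicates, and Gata5 had 20.3% in replicate 1 and 0% in replicate 2. These values are for the 5' end of the gene record and do not cover any other annotated 5' end of these genes. Against genes matched on CpG and GC, of which 35.0% were marked, the excess no longer passed the test (adjusted exact p = 0.775).

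Genes of the contractile and electrical machinery of cardiomyocytes were marked at 9 of 35, 25.7% (14.2 to 42.1), which passed the test neither against other genes (adjusted exact p = 0.198) nor against the cardiac factors (exact p = 0.286, Fisher's exact tests). The marked members with the highest coverage were the ion channel genes Kcnq1 at 95.6% ± 3.08, Scn5a at 93.3% ± 7.11 and Hcn4 at 77.4% ± 0.46, and the giant sarcomere protein gene Obscn at 88.9% ± 15.7. The myosin genes Myh6 and Myh7 had no called base, and Myl2 had 10.3% ± 0.60. With windows of 2.5 kb either side of the 5' end the list passed the threshold (adjusted exact p = 0.00407), as it did with all annotated transcripts' 5' ends (adjusted exact p = 0.0205). The excess of 9.34 points was 15.3 in replicate 1's own list (13 of 35, adjusted exact p = 0.0503), 12.9 in replicate 2's (11 of 35, adjusted exact p = 0.107) and 2.81 over bases called in both (adjusted exact p = 0.706). The difference of cardiac factors from sarcomere genes was 13.6 points and passed in none of 10 alternatives. It ranged from 7.86 in replicate 2's own list to 21.4 with windows of 0.5 kb. None of the 30 housekeeping genes was marked, which allows a share of up to 11.4% (upper Wilson bound), fewer than other genes (adjusted exact p = 0.0158). Actb and Gapdh had 0% in both replicates, and Hprt, on X, had 0% in replicate 1 and 18.0% in replicate 2. In replicate 2's own list 3 housekeeping genes were marked and the test was no longer passed (adjusted exact p = 0.414), nor was it against matched genes (adjusted exact p = 0.0642) or with at least 1000 bp covered (adjusted exact p = 0.15).

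Endothelial and epicardial genes were marked more often than other genes, and for blood cell genes the test was not passed. Of endothelial and endocardial genes 11 of 22 were marked (50%, adjusted exact p = 5.43e-04), including the transcription factors Sox18 at 100% in both replicates, Nfatc1 at 88.7% ± 16.0, Sox7 at 82.5% ± 8.56 and Erg at 82.1% ± 5.69. The surface protein genes Pecam1 and Tek had no called base, and Cdh5 had 10.2% in replicate 1 and 0% in replicate 2. The endothelial excess of 33.6 points over other genes ranged from 21.9 to 37.2 over 13 alternatives and passed in each. It was lowest with a −log10 q of at least 2 (adjusted exact p = 0.0154, Fisher's exact test). Of epicardial and cushion mesenchyme genes 13 of 19 were marked (68.4%, adjusted exact p = 1.58e-06), led by Wt1 at 100% in both replicates and Msx1 at 89.8% ± 0.64. Msx2 reached 80.0% ± 23.1 and Aldh1a2 79.5% ± 18.9. Postn had no called base, Upk3b had 15.7% in replicate 1 alone, and Prrx1 had 26.6% ± 1.24 from replicate peaks without a base in the replicated list. Blood cell genes were marked at 6 of 22 (27.3%, adjusted exact p = 0.198), with Gata2 at 78.6% ± 30.2, Tal1 at 75.5% ± 22.0, Gfi1b at 61.8% ± 14.6 and Klf1 at 46.1% ± 0.74. The erythroid factor gene Gata1 and Hba-a2 had no called base, and Hba-a1 had 10.4% in replicate 1 alone. The excess of 10.9 points was 19 in replicate 1's own list (9 of 22, adjusted exact p = 0.0503) and 17.9 in replicate 2's (8 of 22, adjusted exact p = 0.0728). Against matched genes the blood list passed the threshold (adjusted exact p = 0.0461).

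Among signalling and regulatory families, 18 of 19 Wnt ligand genes were marked (94.7%, adjusted exact p = 5.09e-13), and Wnt5a was the exception. Wnt7b, Wnt7a, Wnt1 and Wnt9b were fully covered in both replicates. Of the genes in the Fgf ligand list 14 of 22 were marked (63.6%, adjusted exact p = 1.90e-06). That list was drawn by gene symbol, and whether each member encodes a secreted ligand was not examined. Fgf3 and Fgf17 were fully covered, Fgf11 stood at 96.0% ± 5.69 and Fgf15 at 95.8% ± 3.36, and Fgf7, Fgf6 and Fgf23 were unmarked. Of genes matched to the Fgf list on CpG and GC 37.3% were marked, and the excess fell from 47.3 to 26.4 points (adjusted exact p = 0.0480). Of genes listed as imprinted, expressed from 1 parental copy in at least some tissues, 12 of 28 were marked (42.9%, adjusted exact p = 0.00152). Slc22a3 stood at 100% in both replicates, Dio3 at 98.6% ± 2.05 and Dlk1 at 95.4% ± 2.12. Whether these genes are expressed from 1 copy in heart was not examined. Slc22a18, Tssc4 and Cd81 were unmarked. In replicate 2's own list the excess of imprinted genes fell from 26.5 to 17.2 points (adjusted exact p = 0.0445). Of cell cycle inhibitor genes 4 of 7 were marked, Cdkn2a at 81.9% ± 25.7, Cdkn2b at 39.8% ± 24.1, Cdkn1a at 20.4% ± 6.43 and Cdkn1c. Coverage at Cdkn1c was 28.9% in replicate 1 and 0% in replicate 2. Cdkn1b, Cdkn2c and Cdkn2d had no called base. The adjusted p of 0.0230 for the cell cycle inhibitor list (Fisher's exact test) was lost in 7 of 13 alternatives. Among them were either replicate's own list, at 0.159 and 0.0543, and rotation of the marks along the gene order, at 0.0565. Of Polycomb group and H3K27 demethylase genes 4 of 29 were marked, Pcgf5, Pcgf1, Cbx8 and Cbx4 (13.8%, adjusted exact p = 1). Replicate 1's own list marked 9 of the 29, more often than other genes, and replicate 2's marked 4, less often, and neither passed the test. The enzyme genes Ezh1 and Ezh2 and their partner Eed had no called base.

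Few olfactory receptor genes had called peaks enough to count as marked, and liver, pancreas and germline genes did not pass the test against other genes. Of 1093 olfactory receptor genes 6 were marked (0.549%, adjusted exact p = 2.18e-75), the highest being Olfr1377 at 44.4% ± 23.7. The replicates' own lists marked 15 and 13, and of genes matched on CpG and GC 4.19% were marked, so the difference, list minus background, shrank from -16.7 to -3.64 points (adjusted exact p = 2.05e-11). Olfr1414 had 30.6% ± 13.8, Olfr95 24.9% ± 3.61 and Olfr63 13.1% ± 1.91, and Olfr1416, Olfr1415 and Olfr1413 were unmarked. Of liver and pancreas secreted protein genes only Sst, the somatostatin gene, was marked, at 78.6% ± 15.1, out of 22 (4.55%, adjusted exact p = 0.272), while the replicates' own lists marked 3 and 2, and Alb and Afp had no called base. Apoa1 had 15.5% in replicate 1 alone. Of germline genes Tdrd1 at 51.5% ± 47.2 and Nanos3 at 35.4% ± 9.12 were marked out of 18 (11.1%, adjusted exact p = 0.799), and Dazl and Sycp1 had no called base. Ddx4 had 17.8% ± 3.11 but none in the replicated list. The replicates' own lists marked 4 and 3 of the 18 germline genes.

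CpG-rich 5' ends were marked somewhat more often than the others, at 1799 of 9741 (18.5%, 95% interval 17.7 to 19.3) against 1767 of 12014 (14.7%, 14.1 to 15.4; exact p = 1.11e-13, Fisher's exact test). The direction depended on where the classes were divided. With a CpG ratio of at least 0.75 and GC of at least 55%, the shares were 15.2% and 16.8% (exact p = 0.00765). In replicate 1's own list the excess of CpG-rich 5' ends was 2.69 points and in replicate 2's 1.41 points (exact p = 0.00766), against 3.76 in the replicated list.

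On X 146 of 948 genes were marked (15.4%, 13.2 to 17.8), against 16.4% of autosomal genes (exact p = 0.42, Fisher's exact test). The share was lower on X with a −log10 q of at least 2, at 11.3% against 14.7% (exact p = 0.00344), and with at least 1000 bp covered, at 5.70% against 9.45% (exact p = 4.57e-05). The replicates differed here more than elsewhere. Replicate 1's own list marked 28.2% of X genes against 21.6% of autosomal genes (exact p = 3.65e-06), and replicate 2's 20.0% against 18.5% (exact p = 0.231). Over X replicate 1 called 1.64 times as many bases as replicate 2, 1.54% against 0.935% of the chromosome, where the 19 autosomes lay between 1.17 and 1.3. The Jaccard index was 19.6% on X and between 31.7% and 41.1% on the autosomes. Called bases move with how permissive a list is, and 1 pair of replicates gives no test of such a difference between chromosomes.

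**Figure D3:**
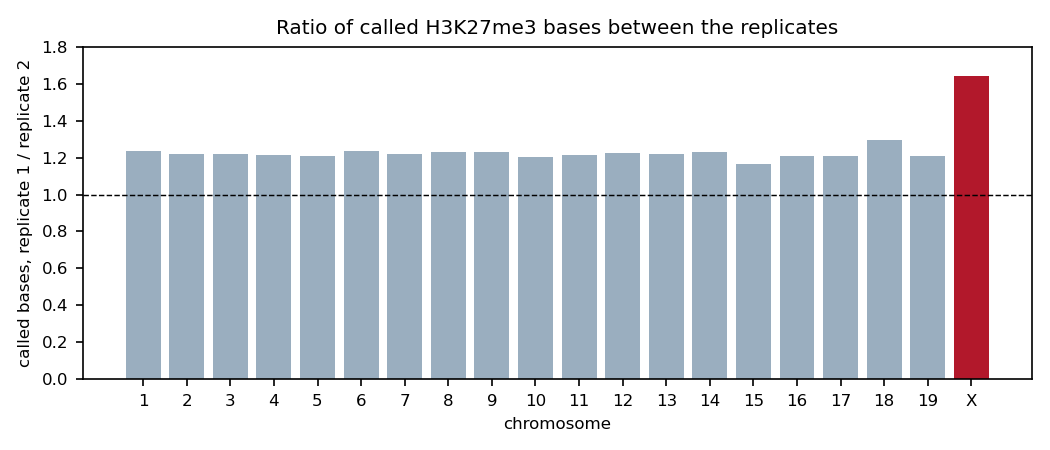
Bases called in replicate 1 divided by bases called in replicate 2 (vertical axis) for each chromosome (horizontal axis), with autosomes in grey, X in red and the dashed line at 1. X stands at 1.64, above the highest autosome, chromosome 18, at 1.3.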

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

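Lists of equal length, as an alternative for the replicate comparisons, and matched genes outside all lists were chosen after seeing the data; the other alternatives were fixed before. Of 335 recomputed values 272 counted as kept: tested differences with the same direction and side of the threshold, counts within 1.5 times the main one, and other values within 1 SD of the replicates (of the circular shifts for overlap) or, for genes shared by the replicates, the 95% binomial interval. Of the 244 tested differences among them, 41 still changed by more than 1.5 times. The excess of non-cardiac over cardiac factors kept its direction and side in 10 of 10 alternatives (40.9 to 58.0 points). Of the 18 lists, 11 did so in 13 of 13, among them the liver and pancreas list, which never passed the threshold. A difference of 0, as for sarcomere genes against matched genes, also counted as kept. Except where a sentence names one, the cause of a change was not tested. Unknown depth limits what an uncalled base shows.

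List differences below are list minus background, in percentage points. Against CpG- and GC-matched genes the excess of cardiac factors was 4.29 (5 without list genes) and no longer passed; that of sarcomere genes was -0.571 without list genes, and the deficit of housekeeping genes, -12 and -11.3, no longer passed. Blood cell genes passed there, at 18.2 and 19.1, and with all transcripts' 5' ends at 21.5. Sarcomere genes passed with all transcripts at 17.7 and 2.5 kb windows at 22.3. Housekeeping genes also failed with at least 1000 bp covered (-9.30) and ranged from -21.9 to -8.54 in single replicates. Polycomb group genes, never past the threshold, changed direction in the pooled list (3.21), with 1 bp covered (6.49), with 2.5 kb windows (6.96) and all transcripts (4.72), and ranged from -4.74 to 9.17 in single replicates. Germline genes ranged from -1.86 to 0.342 there. Cell cycle inhibitors no longer passed with -log10 q of at least 2 (14.0), bases called in both replicates (28.5), at least 1000 bp (5.0), 0.5 kb windows (15.6) or rotations (40.6), nor in single replicates (24.3 to 35.3).

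The CpG difference was -1.55 points with the stricter class. That of X against autosomes was -3.40 with -log10 q of at least 2 and -3.76 with at least 1000 bp, both past the threshold, 0.136 in the pooled list and 1.58 to 6.57 in single replicates. Replicate overlap was 39.4% with -log10 q of at least 2, 36.3% on autosomes and 42.3% with equally many strongest peaks. As shares of peaks it was 41.5% and 53.7% with 1 bp, and 30.3% and 43.4% with 50% covered, for replicates 1 and 2. Marked genes fell to 2021 with at least 1000 bp, where 72.3% were shared by the replicates, against 69.5% with equally many strongest peaks. Bases called in both replicates covered 85.9% of Hoxa, 69.4% of Hoxb, 92.5% of Hoxc and 83.0% of Hoxd. Wide domains numbered 1248 with gaps of at most 3 kb and 33 with none merged. Promoter, exon, intron and outside shares were 14.6%, 11.1%, 37.0% and 37.2% with -log10 q of at least 2, 12.4%, 10.1%, 37.7% and 39.7% in the pooled list, and 9.79 to 10.1%, 8.70 to 9.02%, 38.1 to 38.3% and 42.9 to 43.1% in single replicates.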

Other observations

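The test of cardiac factors against genes matched on CpG and GC was planned. The other tests in this part were chosen after the patterns they bear on had been seen; of these, the ratios on X with equally long lists and outside genes were set before their own values were known.

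Outside the fixed lists, gene families sharing a symbol stem differed in how often they were marked. Of 141 families with at least 15 genes, 13 were marked more often and 12 less often than other genes after adjustment (Fisher's exact test), and 8 and 4 of these also passed with 1000 rotations along the gene order. The synaptotagmins, some of which are calcium sensors of vesicle release, stood highest, with 15 of 17 marked (88.2%, adjusted exact p = 1.11e-08). Syt6, Syt13, Syt16 and Syt2 were among the marked members. Inward rectifier potassium channels (Kcnj) followed with 9 of 15 (60%, adjusted exact p = 0.00276), semaphorins with 11 of 20 (55%, adjusted exact p = 0.00179) and the Galnt glycosyltransferases with 9 of 17 (52.9%, adjusted exact p = 0.00683). Collagen genes were marked at 19 of 43 (44.2%, adjusted exact p = 4.56e-04), orphan Gpr receptors at 27 of 73 (37.0%, adjusted exact p = 4.56e-04), and solute carriers at 94 of 366 (25.7%, adjusted exact p = 1.61e-04). Zinc finger genes named Zfp were marked at 24 of 394 (6.09%, adjusted exact p = 4.31e-08), vomeronasal receptor genes at 0 of 331 (adjusted exact p = 2.23e-24) and mitochondrial ribosomal protein genes of the Mrpl series at 0 of 49 (adjusted exact p = 0.00381). These families were not matched on CpG content.

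Marking did not rise steadily with CpG content. The share of marked genes was 4.78% below a CpG observed/expected ratio of 0.2, 14.8% from 0.2, 31.2% from 0.4, 22.4% from 0.6, 13.2% from 0.8 and 9.20% from 1. Both replicates' own lists had their highest share in the class from 0.4, at 37.8% and 33.4%.

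X carried more called bases in replicate 1 than any autosome did relative to replicate 2, with a ratio of 1.64 against at most 1.3 on the 19 autosomes. With equally many of each replicate's strongest peaks the ratio was 1.52 against at most 1.19, so equal length lowered the autosomes' mean from 1.22 to 1.11 and left X above them, which argues against the longer list and its weakest peaks as the whole cause. Bases outside genes on X had a ratio of 1.59 against at most 1.28, so the excess was not limited to genes. A higher share of female embryos in that pool would bring more copies of X and more inactive X chromosomes together, so the ratios cannot tell these apart, and the sex ratio of the pools is not given. A difference in enrichment between the libraries was not tested and stays open.

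CpG-rich 5' ends on X were marked more often than those on autosomes, at 32.9% against 18.1% in the replicated list (exact p = 1.42e-07), 53.9% against 22.6% in replicate 1 and 41.2% against 18.8% in replicate 2 (Fisher's exact tests). CpG-poor 5' ends on X went the other way in the replicated list, at 9.86% against 15% (exact p = 8.96e-05), and in replicate 2, at 13.3% against 18.2% (exact p = 7.69e-04), and in replicate 1 they stood at 20% against 20.7% (exact p = 0.669). The median fold of the marked CpG-rich ones was lower on X, at 4.12 against 5.30 in replicate 1 and 3.61 against 5.12 in replicate 2. A candidate explanation is the inactive X of female embryos, which carries this mark, and which would leave genes that escape inactivation unmarked. Of 7 escape genes listed, the 4 with CpG-rich 5' ends, Ddx3x, Kdm6a, Eif2s3x and Kdm5c, were unmarked in both replicates. Of 224 other such genes, 123 were marked in replicate 1 (exact p = 0.0436, Fisher's exact test) and 94 in replicate 2, where no test was made. Of the 3 listed genes without a CpG-rich 5' end, Mid1 was marked in replicate 2. The value of Kdm6a was known before that list was written, and without it the test gave an exact p = 0.0947, so 3 genes are too few to decide, and genes active in all cells could be unmarked for other reasons.

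CpG and GC content may account for the excess of marked 5' ends among cardiac factors but not for that among non-cardiac factors. The cardiac excess fell from 22.9 points over all other genes to 4.29 points over matched genes (adjusted exact p = 0.775, Fisher's exact test) and 5 points over matched genes outside all lists. With 28 genes an interval of 23.6 to 57.6% on their share leaves room for a difference of either sign. The excess of cardiac factors in wide domains, 28.6% against 2.22% of other genes, was not tested against matched genes. The non-cardiac factors stayed 70.1 points above matched genes outside all lists, at 91.8% against 21.6% (exact p = 2.67e-40, Fisher's exact test). The heart tissue mixes cell types, so a marked factor could be silent in some cells and active in others, which peak lists cannot show, and no test of this was made.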
